A study of Mus musculus with 16 samples.

How the data were processed

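Single cells were isolated from the hippocampus of 60 mice, stained with 1 hashtag antibody per mouse and sequenced in 8 pooled batches, per the labels. The mice were wild type (WT) or heterozygous for a gene trap in Kmt2d (Kbk, a model of Kabuki syndrome), and they form 10 groups of 6 mice, 3 females and 3 males each. Per the labels' protocols, cells were released with papain in buffers holding the transcription inhibitors actinomycin D and triptolide, and collected from a Percoll gradient. Treated mice received PEG (DMSO 5% and polyethylene glycol 45%), HPBCD (the same with hydroxypropyl-β-cyclodextrin at 0.2 g/mL) or TCF (the same with vorinostat at 5 mg/mL added, an inhibitor of histone deacetylases). The hashtag labels write DCF for the treatment taken here as HPBCD, by elimination, and DMSO_PEG for PEG.

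The deposited matrices hold UMI counts per gene or antibody tag and cell barcode, with no normalization. Per the file headers they were written by Cell Ranger 6.0.1, and per the submitters' processing notes STAR, Seurat 5.1.0 and mm10 were also used. How the submitters chose the barcodes is not stated. Antibody tags for surface proteins in batches 3 and 5, 38 features in each library, held 0 counts, and nothing was computed from them.

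Each of the 100073 barcodes was given to a mouse from the counts of the hashtags that the labels list for its batch. HTODemux in Seurat 5.3.0 was run per batch on centred log-ratio values with a positive quantile of 0.99 and seed 42. It called 36609 singlets, 19535 doublets and 43929 negatives, and only singlets were used. The doublets that it called between mice were thereby removed, though others may remain, and no caller for doublets within a mouse was run. Clusters were left out of the classes where markers of another class passed the limit given below, and milder mixing stayed in, as in cluster 46 (43 microglia-like cells with choroid plexus genes among the leading ones, and choroid plexus markers at 0.2001 times the level of that class). Cells with at least 500 genes and under 10% mitochondrial UMIs were kept, which left 30786 cells, 78 to 1343 per mouse, with 834093 to 45180582 UMIs per mouse. In scanpy 1.11.5 the counts were log-normalised, 2000 variable genes were picked within batches, each gene was centred per batch, and 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2, resolution 1, seed 0) followed. A cluster took the class whose marker list had the highest mean score. It was left out where its leading genes belonged to another class, where markers of another class reached 0.25 times the level seen in that class, or where its median UMI count was under 0.333 times that of its batch without a marker of its own among its leading genes. Classes are called microglia-like, endothelial-like and so on, since they rest on marker genes alone. A total of 3058 cells were left out in this way, with group means between 7.99% and 11.3%.

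The replicate was the mouse. UMI counts were summed per mouse and class over mice with at least 20 cells. Genes kept by filterByExpr were tested with edgeR 4.0.16 (TMM, glmQLFTest, two-sided) in a model of group, sex and batch fitted over all mice. Benjamini-Hochberg adjusted p under 0.05 within a class and comparison counted as changed. CPM are the cpm values of edgeR on TMM-scaled totals, given as mean ± SD over mice, and log2 fold changes are given with a standard error where useful. There were 15 comparisons (11 in choroid-plexus-like cells), 13 of a pair of groups and the difference of the vorinostat effect between genotypes against untreated and against HPBCD mice. Other classes were tested where both groups had 3 mice. Shares of cells were compared with an exact two-sided permutation test over the 59 mice with at least 100 filtered singlets.

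Genes are named by a fixed rule. Among genes past the threshold, without predicted models, the 12 largest rises and 12 largest falls with a mean of at least 20 CPM in a compared group are named. Where none passed, the 5 smallest p are named and said not to pass. In other classes the numbers are 3 and 3. Kmt2d is named in every comparison of genotypes, as is any member of the gene lists. The design, this rule, the 26 gene lists and most alternatives were fixed before the data were examined. The lists are homeostatic microglia, disease-associated microglia, interferon response, antigen presentation, inflammatory NF-κB, immediate-early, heat shock, cholesterol synthesis, cholesterol efflux, lysosome, complement, phagocytosis, TGF-β signalling, nuclear oxidative phosphorylation, mitochondrially encoded, ribosomal proteins, glycolysis, cell cycle, histone deacetylases, response to histone deacetylase inhibitors, H3K4 methylation machinery, immature neuron, myelin, reactive astrocyte, blood-brain barrier and sex-linked genes. For each list the members past the threshold over all genes are counted, and beside them those past it when adjusted over the list alone. Lists were also tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 and with the correlation estimated from the data.

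The test was checked on simulated data with the same mice, batches and depths. In microglia-like cells of the 1-month genotype comparison it recovered 49.3% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 97.0% of those changed 4-fold. Between vorinostat-treated and untreated Kbk mice it recovered 47.8%, 85.1% and 100%, and in endothelial-like cells of the 1-month genotype comparison 32.8%, 73.1% and 90.9%. Microglia-like cells numbered 49 to 521 per mouse with 436874 to 5431376 UMIs, so single genes changed under 1.5-fold were often not detectable. To see what groupings without an effect give, each count was recomputed for 30 splits of the compared mice into groups of the same sizes, the real split included, with group labels shuffled under a fixed seed.

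Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE scaling, no low-count filter, no batch term, the replicate number as a block, only the compared groups, a margin rule for hashtags (top tag at least 20 counts and 70%), a stricter cell filter (1000 genes, 5%), a minimum of 50 cells, a resolution of 0.5, and each batch left out. Chosen after seeing the data were a hashtag rule scaled to the ambient level of each tag (pseudocount 5, at least 20 adjusted counts, log2 of the top over the second tag at least 2), leaving out batches 2 and 3, leaving out single mice, leaving out 2 mice whose Kmt2d goes against their labels, and the average of the genotype difference over 5 settings. Hashtag calls were checked against transcripts of sex-linked genes. In batch 2 the cells given by HTODemux to females Kbk_3m_TCF F_2, Kbk_3m_TCF F_3 and Kbk_3m_HPBCD F_1 held 37.9%, 33.3% and 27.0% cells with transcripts of the other sex only, and in batch 3 those given to WT_3m_Un F_2 held 31.4%. Where both HTODemux and the margin rule called a cell, they named the same mouse in 95.1% of 19657 cells, with 44.8% in batch 3. There the margin rule gave WT_3m_Un M_2 2533 filtered cells against 78 by HTODemux. Of those 2533 cells 19.2% held transcripts of the other sex only, so the margin rule is no sounder in this batch. Other tools were R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.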

Results

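Hippocampal cells of 60 mice were dominated by microglia and by cells of the vessel wall and choroid plexus. A total of 30786 cells passed the filters, and their clusters carried the markers of 11 classes. Microglia-like cells (Aif1, Crybb1 and Trem2) numbered 12635, endothelial-like cells (Cldn5 and Itm2a) 4788, choroid-plexus-like cells (Ttr, Kl and Folr1) 4384 and mural-like cells (Tagln, Acta2 and Myh11) 2043. Smaller classes were oligodendrocyte-like (Mog, 901), astrocyte-like (Aqp4 and Gja1, 847), border-macrophage-like (Pf4, Mrc1 and Cd163, 743), precursor cells of oligodendrocytes (638), neuroblast- and progenitor-like (Sox11 and Dcx, 342), ependymal-like (293) and fibroblast-like cells (114). All 60 mice had at least 20 microglia-like cells, against 56 with as many endothelial-like, 45 with mural-like and 42 with choroid-plexus-like cells, and the other classes held too few mice to compare genes. Microglia-like cells of different batches mostly sat in different clusters. In batches 1, 2, 3 and 5 clusters 3, 5, 9 and 7 took 92.8%, 95.9%, 89.4% and 89.4% of them, and in batch 8 cluster 0 took 80.3%. Cluster 0 also took 64.7% in batch 6 and 63.8% in batch 7, and cluster 2 took 52.5% in batch 4. Batches 4 and 8 held wild-type (WT) mice alone, 8 and 4 of them, and batch 2 held 7 Kbk mice and 1 wild-type mouse. Some compared groups thus sat in different clusters. With vorinostat, Kbk cells were mostly in clusters 3 and 5 (40.1% and 38.5%) and wild-type cells in clusters 0 and 2 (42.3% and 34.6%). Untreated 3-month cells were most often in cluster 3 in Kbk (45.3%) and in wild type (45.0%).

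Shares of the cell classes were compared by permutation tests in which no single share could pass after adjustment, so they leave differences open. Over 59 mice, microglia-like cells made up 45.9% ± 12.9% (mean ± SD), endothelial-like cells 16.8% ± 5.57%, choroid-plexus-like cells 14.4% ± 12.2% and mural-like cells 7.77% ± 3.65%. Astrocyte-like cells took 3.71%, oligodendrocyte-like cells 3.64%, their precursors 2.60% and border-macrophage-like cells 2.50%. Of 143 exact two-sided permutation tests of shares, 0 passed after adjustment (smallest adjusted p = 0.989, smallest exact p = 0.0346), 3 had an unadjusted p under 0.05, and the smallest p that 6 against 6 mice allow is 0.00216, too large for 1 of 143 tests to pass alone. Mural-like cells were among these 3, at 9.61% ± 2.55% in untreated 3-month Kbk mice and 6.52% ± 1.31% in their wild-type counterparts (exact p = 0.0433).

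Kmt2d, the histone H3K4 methyltransferase gene that carries the gene trap, was lower in Kbk mice in each of the 4 classes tested, with p adjusted here over these 4 values. Adjusted over all genes of a class, it passed in microglia-like and endothelial-like cells but not in mural-like or choroid-plexus-like ones. In microglia-like cells it averaged 39.4 ± 8.88 CPM over 30 Kbk mice and 65.6 ± 11.3 CPM over 30 wild-type mice (log2 fold change −0.60, SE 0.07, adjusted p = 2.46e-11), or 65.8% of wild type. Endothelial-like cells gave −0.63 (37.2 ± 12.8 against 62.5 ± 12.1 CPM, adjusted p = 1.69e-06), mural-like cells −0.45 (36.0 ± 13.6 against 49.3 ± 16.04 CPM, adjusted p = 0.0124) and choroid-plexus-like cells −0.23 (15.8 ± 4.37 against 21.4 ± 4.23 CPM, adjusted p = 0.0269). By group, microglia-like cells of 1-month mice held 43.4 ± 9.72 CPM in Kbk and 60.1 ± 13.3 in wild type, and untreated 3-month mice 41.5 ± 12.6 and 63.5 ± 14.1. Vorinostat-treated Kbk mice stayed at 36.2 ± 6.21 CPM.

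In a pair of libraries of batch 1, Kmt2d went against the label. The library labelled Kbk_3m_Un M_1 held 60.0 CPM, above the 27.2 to 57.0 CPM of the other 29 Kbk mice, and the library labelled WT_3m_Un M_1 held 39.9 CPM, under the 44.3 to 94.8 CPM of the other 29 wild-type mice. Both are male, untreated and 3 to 4 months old. Genotype genes drawn from the other 7 batches, for each batch in turn, were then used to place each mouse between wild type (0) and Kbk (1). Over the 860 genes that served batch 1 in microglia-like cells the library labelled Kbk_3m_Un M_1 stood at 0.2496 (other Kbk mice 0.608 to 1.22) and the library labelled WT_3m_Un M_1 at 0.896 (other wild-type mice −0.339 to 0.550). Over 74 genes in endothelial-like cells they stood at 0.176 and 0.899. In microglia-like cells 57 of the other 58 mice lay on the side of their label, all but WT_1m_Un M_1 at 0.550. In batch 1 the other 4 Kbk mice stood at 0.917 to 1.15 and the other 2 wild-type mice at 0.202 and 0.550. Both libraries keep their labels throughout, and microglia-like values without them are given where a comparison rests on untreated 3-month mice.

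**Figure D1:**
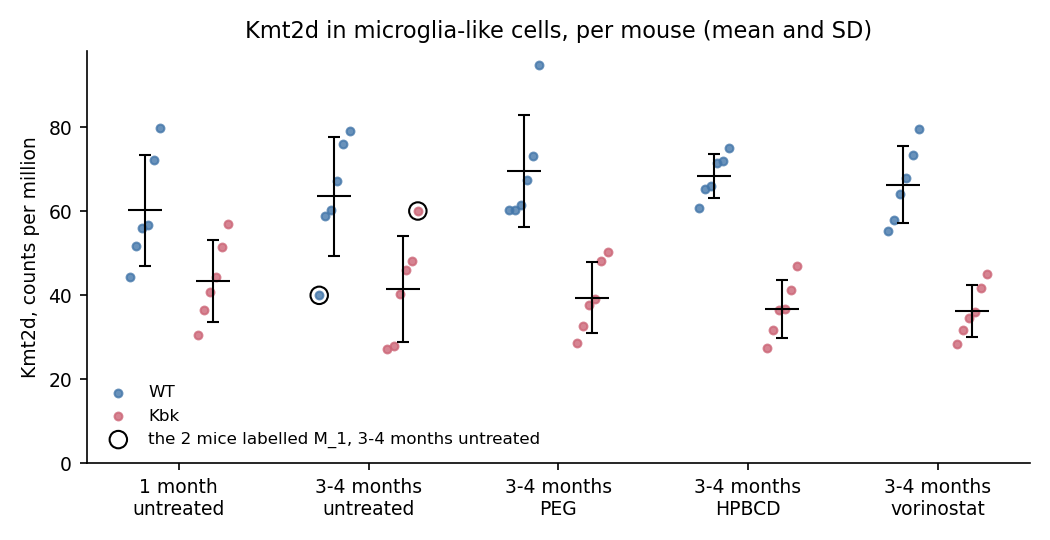
Kmt2d in microglia-like cells in CPM, 1 point per mouse, in wild-type (WT) and Kbk mice by age and treatment. Bars show mean and SD over 6 mice, and circles mark the 2 libraries whose level goes against the label.

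**Figure D2:**
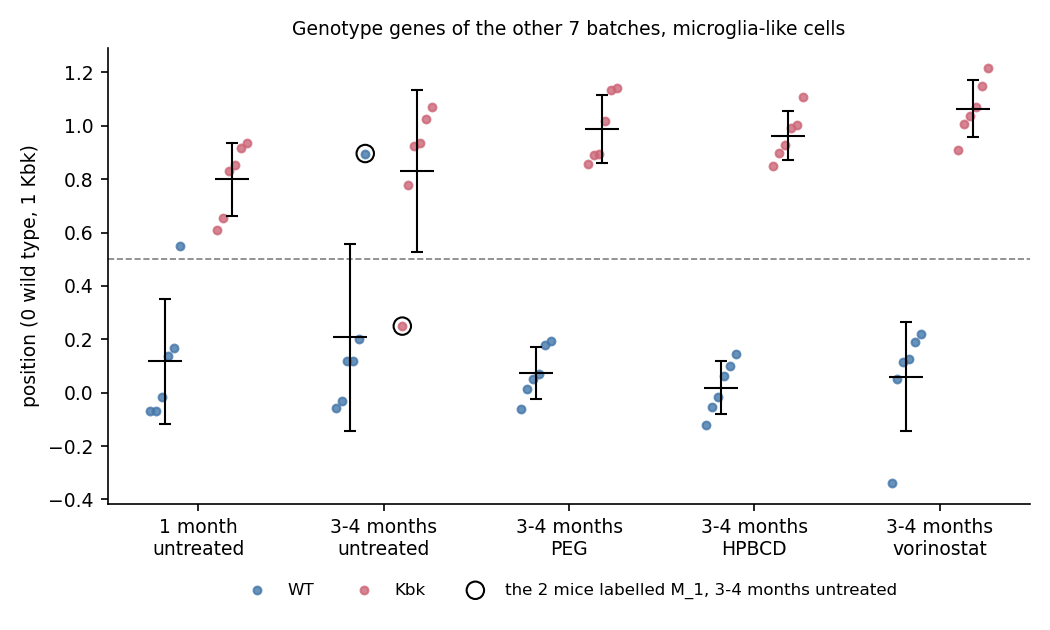
Position of each mouse between wild type (0) and Kbk (1) over genes that differ between the genotypes in the other 7 batches (860 genes for batch 1), microglia-like cells. Points are mice, bars show mean and SD over 6 mice, and circles mark the library labelled WT_3m_Un M_1 (0.896) and the library labelled Kbk_3m_Un M_1 (0.2496).

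At 1 month, microglia-like cells of Kbk mice held less RNA of Lyz2, Apoe and Mrc2, among other genes, than wild-type cells did. Lower genes included those for lysozyme (Lyz2), the lipid carrier apolipoprotein E (Apoe), the collagen receptor Mrc2, the surface glycoprotein Cd52, the lysosomal reductase Ifi30, the immune-receptor adaptor Lat2, the leukocyte protein Lsp1, the granule proteoglycan Srgn, Cd79b and Oaf. Genes higher in Kbk included the RNA-binding protein gene Khdrbs3, Tmem44, the cytokine gene Kitl, the glycosyltransferase genes Galnt12 and Galnt7, the adhesion receptor gene Adgrl2, the leukotriene receptor gene Cysltr1, the iron exporter gene Slc40a1, the chemokine gene Ccl9, Mlph, Atxn1 and Enc1. Of 10594 genes tested, 76 changed, 25 higher and 51 lower in Kbk (938 at an unadjusted p under 0.05, 71 by DESeq2). Mrc2 fell from 24.5 ± 7.36 to 4.75 ± 3.75 CPM (log2 fold change −2.33, adjusted p = 8.06e-07), Cd52 from 398 ± 44.6 to 198 ± 46.1 (−1.04, adjusted p = 5.89e-06) and Lyz2 from 201 ± 82.1 to 55.9 ± 10.3 (−1.69, adjusted p = 8.00e-05), each under the wild-type median in 6 of 6 Kbk mice. The wild-type mouse WT_1m_Un M_1 held 45.4 CPM of Lyz2, as low as Kbk mice, against 188 to 270 in the other 5. Apoe fell from 1709 ± 907 to 825 ± 183 CPM (−0.94, adjusted p = 0.00206), Lat2 from 115 ± 9.55 to 55.3 ± 16.1 (−1.14, adjusted p = 6.74e-04) and Ifi30 from 149 ± 36.0 to 67.8 ± 14.6 (−1.08, adjusted p = 0.00131). The other falls named were Lsp1 (−1.24), Cd79b (−0.94), Srgn (−0.91), Oaf (−0.85) and Kmt2d itself (−0.45, adjusted p = 0.0485, lower in 5 of 6 Kbk mice).

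Khdrbs3 rose from 74.6 ± 27.9 to 151 ± 62.9 CPM (log2 fold change 1.04, adjusted p = 7.89e-05, 5 of 6 Kbk mice) and Adgrl2 from 31.6 ± 3.54 to 49.3 ± 6.27 (0.62, adjusted p = 3.40e-04, 6 of 6). Tmem44 (0.82), Kitl (0.65), Galnt12 (0.64), Mlph (0.61), Galnt7 (0.56), Atxn1 (0.54), Enc1 (0.49), Cysltr1 (0.46), Slc40a1 (0.46) and Ccl9 (0.43) rose as well. Both genotypes shared 4 batches, and within them each gene named so far as changed at 1 month kept its direction in 4 of 4, except Lyz2 (3 of 4). A pair of chemokine genes, Ccl5 (3 of 4 batches) and Cxcl10 (1 of 4), passed on the strength of few mice. Ccl5 averaged 1.42 ± 2.57 CPM in Kbk and 72.0 ± 111 in wild type, with 119.4 CPM in WT_1m_Un M_1 and 279.4 in M_2, and Cxcl10 was at 0 in Kbk and at 128.8 CPM in WT_1m_Un M_1. Summed markers of T and NK cells in these microglia-like cells stood at 0.484 CPM in Kbk and 56.8 ± 137 in wild type (0 called), and those of monocytes at 65.9 ± 9.26 and 87.2 ± 21.9 (1 called). The T and NK value in wild type rests on few mice, since its SD exceeds its mean. Without WT_1m_Un M_1, 50 genes changed, 33 of them shared with the 76. Without batch 2, 4 or 5 the counts were 36, 134 and 41, and without WT_3m_TCF M_1, a mouse of neither group that enters the shared fit, 144.

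**Figure D3:**
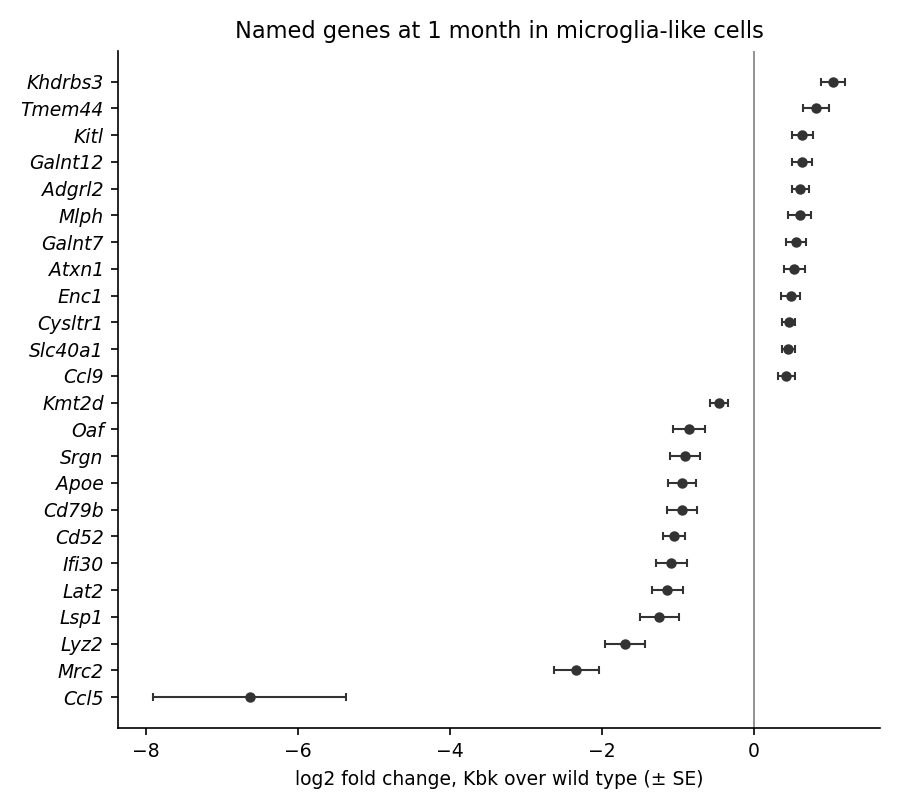
Genes named at 1 month in microglia-like cells of 6 Kbk and 6 wild-type mice. Points show the log2 fold change of Kbk over wild type and bars the standard error from the edgeR fit.

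Among gene lists, disease-associated microglia genes had 5 of 23 measured members lower in Kbk (Lyz2, Apoe, Cd68, Ctsl and Fth1, with Cd68 along that direction in 3 of 4 shared batches) and 0 higher, or 8 lower adjusted over the list alone (adjusted p = 0.406 with an estimated correlation). Antigen presentation lost H2-T23 (−0.33) and H2-Q7 (−2.16, lower in 3 of 4 shared batches), 2 of 14 members (1 higher and 8 lower adjusted over the list alone). Phagocytosis lost the antibody receptor Fcgr2b (−0.51) and the integrin Itgb2 (−0.37), 2 of 23 (2 higher and 6 lower adjusted over the list alone). Reactive astrocyte genes lost S100a10 (−1.49) and Cxcl10, 2 of 7 (1 and 3 adjusted over the list alone), lysosome genes Ctsl, 1 of 27 (0 and 4), cholesterol efflux genes Apoe, 1 of 15 (0 and 2), and interferon response genes Cxcl10, 1 of 20 (0 and 2). Tgfbr1, a receptor in both the homeostatic microglia list (25 measured) and the TGF-β list (14 measured), was the 1 member of either that rose (0.22), against 3 and 2 risen adjusted over the list alone. Tpi1 (0.36) was the 1 of 16 glycolysis genes that rose, and Kmt2d the 1 of 19 genes of the H3K4 methylation machinery that fell. Inflammatory NF-κB genes (17 measured) and mitochondrially encoded genes (13 measured) had 0 members past the threshold over all genes and 1 lower each adjusted over the list alone.

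At 3 to 4 months, the genotype difference in untreated microglia-like cells pointed the same way as at 1 month for most of the 1-month genes, but 0 genes passed the threshold while both libraries that go against their labels were included. By edgeR 590 genes had an unadjusted p under 0.05, and DESeq2 called 2. The smallest p were those of Mrc2 (−1.40, 6.46 against 18.6 CPM) and the transcription factor gene Hlf (1.09, 53.7 against 21.4 CPM), both at an adjusted p = 0.0880, Lyz2 (−1.02, adjusted p = 0.106), and Mrc1 (−2.27), the adenylyl cyclase gene Adcy8 (1.27) and Kmt2d (−0.51), all at an adjusted p = 0.204. None of these passed. Each of these genes kept its direction in 3 of 3 shared batches. The wild-type level of Mrc1 rests largely on the library labelled WT_3m_Un M_1. In these same mice, 25 of the 25 genes higher at 1 month and 46 of the 51 lower at 1 month kept their sign. Of the gene lists, 0 had a member past the threshold over all genes. Adjusted over the list alone, 4 phagocytosis, 2 disease-associated, 2 antigen presentation, 2 lysosome genes and Kmt2d were lower and 1 cholesterol efflux gene was higher.

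Without the library labelled Kbk_3m_Un M_1 and the library labelled WT_3m_Un M_1, 84 genes changed between the 3-month genotypes (29 higher and 55 lower, 1025 at an unadjusted p under 0.05), 25 of them shared in direction with the 1-month genes. Leaving out the library labelled Kbk_3m_Un M_1 alone gave 32, and the library labelled WT_3m_Un M_1 alone 16, while leaving out all of batch 1 gave 53. Other mice and batches left out gave at most 2 (WT_1m_Un M_1, and 1 for WT_3m_TCF M_1 or batch 4). Lyz2 fell to 102 ± 26.8 from 337 ± 58.2 CPM (−1.67, adjusted p = 1.01e-07, 5 against 5 mice), Ifi30 to 60.9 ± 7.55 from 154 ± 43.8 (−1.32, adjusted p = 9.58e-06) and Kmt2d to 37.9 ± 9.85 from 68.2 ± 9.08 (−0.92, adjusted p = 3.91e-08). Also lower were Igfbp4 (−1.66), the leukotriene-producing enzyme Alox5 (−1.43), Ebi3 (−1.17), Hacd4 (−1.15), Lat2 (−0.93), Neurl1a (−0.91), Oaf (−0.89), Srgn (−0.80) and Cd52 (−0.76). The collagen gene Col6a3 rose to 28.9 ± 6.30 from 9.84 ± 2.56 CPM (1.63, adjusted p = 9.70e-04), Hlf to 57.2 ± 3.96 from 18.9 ± 6.66 (1.45, adjusted p = 9.20e-04) and the actin crosslinker gene Actn1 to 72.4 ± 18.0 from 30.6 ± 4.55 (1.29, adjusted p = 1.89e-04). With them rose Pcp4 (1.31), Gpr165 (1.20), Tmem44 (1.17), Casc4 (0.90), Trp53i11 (0.81), S1pr1 (0.69), Khdrbs3 (0.69), Fry (0.67) and Peak1 (0.62). Part of this gain is built in, because both libraries were doubted on the levels of genotype genes.

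Without both libraries, 3 of 23 disease-associated genes (Lyz2, Cd68 and Ctsl), 3 phagocytosis genes (Fcer1g, P2ry6 and Itgb2), 2 lysosome genes (Ctsh and Ctsl), the immediate-early gene Junb and the reactive astrocyte gene S100a10 were lower in Kbk at 3 to 4 months. Adjusted over the list alone, 1 disease-associated gene was higher and 5 lower, 5 phagocytosis, 4 lysosome and 8 heat shock genes were lower, and 1 homeostatic gene was higher.

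**Figure D4:**
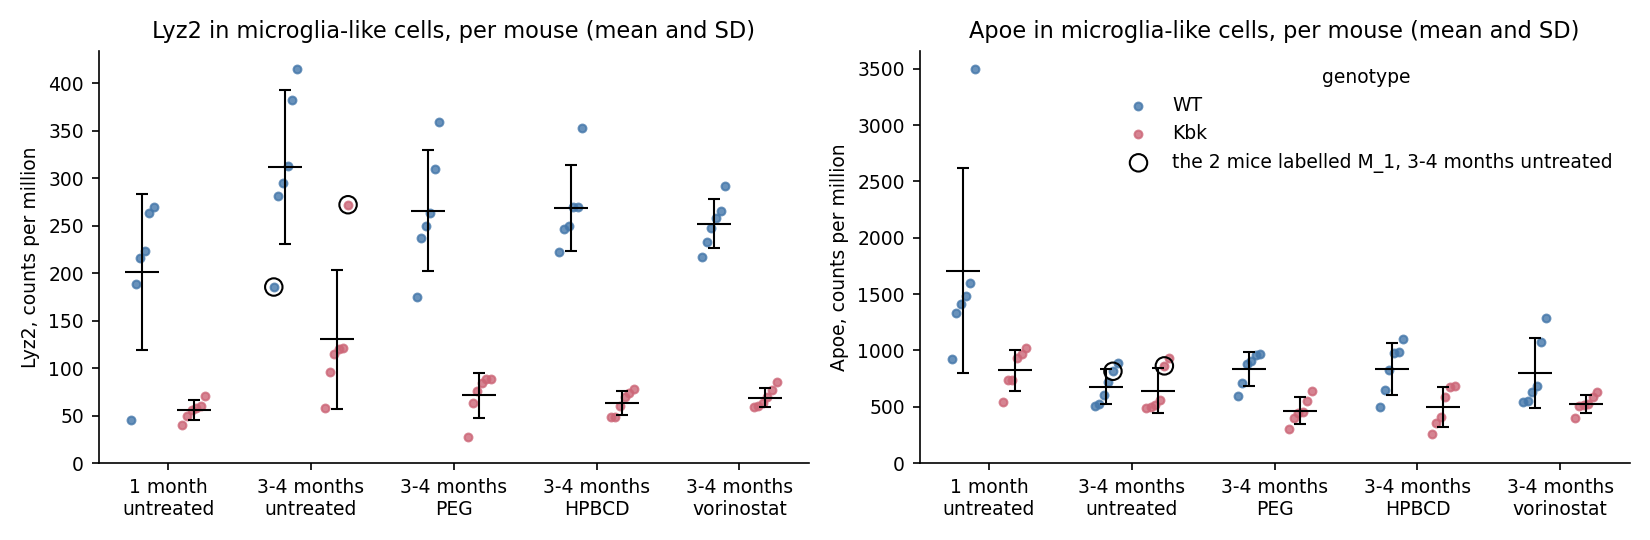
Lyz2 (left) and Apoe (right) in microglia-like cells in CPM, 1 point per mouse, in wild-type (WT) and Kbk mice by age and treatment. Bars show mean and SD over 6 mice, and circles mark the library labelled WT_3m_Un M_1 (Lyz2 185 CPM) and the library labelled Kbk_3m_Un M_1 (272 CPM).

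Vorinostat, the histone deacetylase inhibitor, left no gene past the threshold in microglia-like cells of Kbk mice, whether set against untreated mice or against its HPBCD vehicle. Against untreated mice edgeR called 0 genes (371 at an unadjusted p under 0.05, 0 by DESeq2), and 0 without both libraries of doubtful label, with 1 gene without batch 3 or batch 8. The smallest p belonged to the RNA-processing gene Zc3h3 (−0.79, 13.8 ± 1.52 against 21.4 ± 4.38 CPM, adjusted p = 0.0900, lower in 6 of 6 mice and in 2 of 2 shared batches), followed by Rgs12 (1.27), Myo1g (−1.17), Cd79b (−0.93) and Slc38a3 (1.70), all at an adjusted p = 0.759. Against HPBCD, 0 genes passed (340 at an unadjusted p under 0.05, 1 by DESeq2), with the smallest p for Relch (−0.44), Il10ra (−0.28), Sertad1 (−0.92), Eftud2 (0.45) and Pcdhga12 (1.07), none past the threshold. Of the cells given to Kbk_3m_TCF F_2 and F_3 and Kbk_3m_HPBCD F_1, 37.9%, 33.3% and 27.0% held transcripts of the other sex only. Cells of other mice may thus blur these comparisons, and the simulated recovery did not include such cells. The list of genes that respond to histone deacetylase inhibitors had 0 members past the threshold in either comparison, and adjusted over the list alone 1 was lower against HPBCD. Against untreated mice 2 disease-associated genes and 1 interferon response gene were lower adjusted over the list alone. Lyz2 was among them (69.05 ± 10.3 against 130.4 ± 73.4 CPM), and its untreated level is raised by the doubted library labelled Kbk_3m_Un M_1. The 10 measured histone deacetylase genes, the 38 nuclear genes of oxidative phosphorylation and the 5 immature neuron genes held no changed member in any of the 15 comparisons, over all genes or over the list alone.

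The vehicles also left Kbk microglia-like cells without a changed gene, with the same limit from cells of other mice. HPBCD against PEG gave 0 (376 at an unadjusted p under 0.05, 1 by DESeq2), with Prpf3 (−0.66), Htra2 (0.35), the stress-response gene Atf3 (−1.38), Gcc1 (−0.81) and Clcn6 (0.72) at the smallest p, and 1 immediate-early gene lower adjusted over the list alone. PEG against untreated mice gave 0 (534 at an unadjusted p under 0.05, 0 by DESeq2) and 0 without both libraries of doubtful label (445), with H2afv (0.42), Lmnb1 (1.24), Prkcd (−0.31), Ppil2 (−0.36) and Chst1 (−1.79) at the smallest p. There, 9 cell cycle genes were higher (adjusted p = 0.406 with an estimated correlation) and 3 disease-associated genes lower adjusted over the list alone.

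In wild-type microglia-like cells, the chemokine gene Ccl2 was lower with vorinostat than with HPBCD and higher with HPBCD than with PEG by edgeR. Under the margin rule and under the ambient-scaled rule for hashtags, both comparisons gave 0 genes. Ccl2 averaged 3.42 ± 2.56 CPM with vorinostat, 31.2 ± 31.0 with HPBCD and 8.64 ± 8.59 with PEG. It was the 1 gene past the threshold for vorinostat against HPBCD (−2.54, adjusted p = 0.0201, lower in 6 of 6 mice and 2 of 2 batches, 599 genes at an unadjusted p under 0.05), and DESeq2 called 1 gene, another one. The call did not pass without WT_3m_TCF M_1 or without batch 4, 5 or 6 (0 genes). HPBCD against PEG changed 6 genes, 3 higher and 3 lower (418 at an unadjusted p under 0.05, 1 by DESeq2), among them Ccl2 (2.04, adjusted p = 0.0266), the cytokine gene Il1b (2.58), and the zinc finger gene Zfp738 (−0.62, 21.9 ± 4.10 against 32.5 ± 5.26 CPM, adjusted p = 0.0266), with Ccl2 and Zfp738 along the same direction in 4 of 4 shared batches. Without batch 1, 3, 4, 5, 6 or 8 the count was 3, 1, 1, 1, 2 and 0. The interferon-induced Cxcl9 and Cxcl10 passed through WT_3m_PEG M_2 alone, at 129.3 and 84.6 CPM, with Cxcl9 at 0 in HPBCD mice. Of 17 NF-κB genes, 2 thereby rose from PEG to HPBCD (3 adjusted over the list alone, adjusted p = 0.490 with an estimated correlation), and Ccl2 was the 1 that fell from HPBCD to vorinostat.

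Vorinostat against untreated wild-type mice gave 0 genes (585 at an unadjusted p under 0.05, 0 by DESeq2). The smallest p were those of Tmem154 (3.44, 13.5 ± 25.9 against 1.38 CPM, with 66.1 CPM in WT_3m_TCF M_1), the RNA-binding protein gene Rbms1 (0.72), P4ha1 (−0.57), the glutamate transporter gene Slc1a3 (−0.42) and Mid1ip1 (0.39), with adjusted p from 0.332 to 0.543. Without the library labelled WT_3m_Un M_1 and the library labelled Kbk_3m_Un M_1, the protease gene Klk8 passed (−0.62, 111.9 ± 20.3 against 158.5 ± 17.3 CPM, adjusted p = 0.0474). Without batch 1 or batch 7 there were 3 genes, and 1 without WT_1m_Un M_1. PEG against untreated gave 0 (423 at an unadjusted p under 0.05, 0 by DESeq2) and 0 without both libraries (418), with Zmym5 (−0.44), Tpm4 (0.53), Prpf3 (0.72), Rbms1 (0.65) and Capg (0.82) at the smallest p, and these groups shared 1 batch. Adjusted over the list alone, vorinostat against untreated mice showed 3 antigen presentation, 2 homeostatic, 2 sex-linked, 1 lysosome and 1 reactive astrocyte genes lower and 2 cell cycle genes higher. Against HPBCD it showed 3 glycolysis and 2 myelin genes and 1 lysosome gene lower, 1 disease-associated, 1 phagocytosis and 1 cholesterol synthesis gene higher, and 1 immediate-early gene higher with 2 lower. HPBCD against PEG showed 3 mitochondrially encoded genes higher, and PEG against untreated mice 1 gene of the response to histone deacetylase inhibitors higher and 2 sex-linked genes lower.

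No single gene in microglia-like cells differed past the threshold between the genotypes in its response to vorinostat. Tested as an interaction, the difference against untreated mice gave 0 genes (425 at an unadjusted p under 0.05, 0 by DESeq2) and 0 without both libraries of doubtful label (411), with the smallest p for Rbms1 (−1.15, adjusted p = 0.141), Zc3h3 (−0.99), Tsix (1.17), Vangl1 (1.64) and Gsdme (−1.07), and with 2 genes without batch 7. Against HPBCD it gave 0 (471 at an unadjusted p under 0.05, 1 by DESeq2), with Tmem144 (0.68), Tpi1 (0.58), Tmem132a (1.87), Tnfrsf11a (−0.58) and Med24 (1.23), all at an adjusted p = 0.518. Adjusted over the list alone, 5 glycolysis genes were higher in the interaction against HPBCD (adjusted p = 0.443 with an estimated correlation), beside 1 blood-brain barrier gene. Against untreated mice 2 glycolysis genes and 1 sex-linked gene were higher, and 1 disease-associated, 1 interferon response and 1 cholesterol efflux gene lower.

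Vorinostat-treated Kbk mice still differed from untreated wild-type mice, in part at the genes changed at 1 month. In microglia-like cells 54 genes changed, 21 higher and 33 lower (965 at an unadjusted p under 0.05, 62 by DESeq2). Lyz2 fell from 312 ± 80.9 to 69.0 ± 10.3 CPM (−2.01, adjusted p = 1.43e-06), and with it Ifi30 (−1.25), Hacd4 (−1.04), Cd79b (−1.03), Klc4 (−0.85), Neurl1a (−0.85), Pkdcc (−0.74), the transcription factor gene Cebpb (−0.68), Tmem176a (−0.66), the metal-responsive factor gene Mtf1 (−0.65), Gmfg (−0.62) and Kmt2d (−0.57, adjusted p = 0.0196). Actn1 rose from 34.5 ± 10.3 to 83.7 ± 11.9 CPM (1.12, adjusted p = 0.00124), together with Hlf (1.15), Tmem44 (0.97), the cadherin gene Cdh23 (0.93), Tspan18 (0.91), Casc4 (0.81), the sialic acid enzyme gene Cmas (0.72), the lipid receptor gene S1pr1 (0.71), Slco4a1 (0.64), Nbea (0.61), Tspan7 (0.61) and Bbs9 (0.57). Every one of these held in 6 of 6 vorinostat-treated mice and in 2 of 2 shared batches. With different mice, 10 genes were lower both here and at 1 month (Lyz2, Mrc2, Ifi30, Cd79b, Ctsl, Fcgr2b, Gmfg, Kmt2d, Rassf4 and Tmem176a), where 0.159 would be shared by independent lists, and Tmem44 and Tspan7 were higher in both (0.0496). Both comparisons come from the same fit and share its batch terms, so independent lists set too low a baseline. The mannose receptor gene Mrc1 passed as well (−3.58, 3.00 ± 1.65 against 31.1 ± 55.5 CPM), through the 144 CPM of the library labelled WT_3m_Un M_1, and summed border macrophage markers went with it (5.43 against 32.5 CPM).

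In this comparison the phagocytosis list lost P2ry6 (−0.53), Fcgr2b (−0.43) and Fcer1g (−0.22), 3 of 23 (4 higher and 6 lower adjusted over the list alone). Disease-associated genes lost Lyz2 and Ctsl (1 higher and 8 lower adjusted over the list alone), lysosome genes Ctsl and Ctsh (2 lower) and immediate-early genes Zfp36 (−0.53, 3 lower). Homeostatic genes had 0 past the threshold, with 6 higher and 1 lower adjusted over the list alone (adjusted p = 0.685 with an estimated correlation), and heat shock genes 0, with 8 lower (adjusted p = 0.496 with an estimated correlation). Also adjusted over the list alone, 1 antigen presentation gene was higher and 4 lower, 2 TGF-β genes were higher, 1 gene of the response to histone deacetylase inhibitors was higher and 2 lower, 1 complement and 1 blood-brain barrier gene were higher, and 2 reactive astrocyte genes and 1 cholesterol efflux gene were lower. Without the library labelled WT_3m_Un M_1 the count was 147, and without it and the library labelled Kbk_3m_Un M_1 142 (55 higher and 87 lower, 48 shared with the 54). Without WT_3m_TCF M_1 it was 151 and without WT_1m_Un M_1 84, both mice of neither group, and without batch 2, 3 or 7 it was 13, 23 and 28.

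From 1 month to 3 to 4 months, the protease gene Klk8 rose and Apoe fell in wild-type microglia-like cells. A total of 116 genes changed, 46 higher and 70 lower with age (1108 at an unadjusted p under 0.05, 103 by DESeq2). Klk8 rose from 49.5 ± 13.9 to 140 ± 47.4 CPM (1.51, adjusted p = 6.09e-08, 5 of 6 mice and 3 of 3 batches), Mlph from 44.5 ± 11.2 to 87.3 ± 9.21 (1.11, adjusted p = 6.81e-07) and Lrrc3 by 0.64. Ablim1 (1.16), Cdc42ep3 (1.07), the junction protein gene Jam3 (0.93), the transcription factor gene Prdm1 (0.92), Amotl1 (0.84), Smpdl3a (0.68), Hebp1 (0.64), Galnt7 (0.60) and Frrs1 (0.55) rose as well. Apoe fell from 1709 ± 907 to 678 ± 157 CPM (−1.47, adjusted p = 6.18e-07) and the peptide receptor gene Ramp1 from 132 ± 29.1 to 57.9 ± 20.9 (−1.04, adjusted p = 7.34e-05). With them fell the galectin gene Lgals1 (−1.63), the nuclear lamina gene Lmnb1 (−1.22), Pcp4 (−1.16), Emp3 (−1.02), the chromosome condensation gene Smc4 (−0.89), the kinase gene Fyn (−0.89), the actin-capping gene Capg (−0.82), Tpm4 (−0.75) and Hmgb2 (−0.69), and Cxcl10 through WT_1m_Un M_1 alone. Of 81 ribosomal protein genes 14 fell and 0 rose, or 67 fell adjusted over the list alone (adjusted p = 0.451 with an estimated correlation). Of 20 cell cycle genes, Cdk1 (−1.84) and Hmgb2 fell, or 10 adjusted over the list alone (adjusted p = 0.490 with an estimated correlation).

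Other lists moved at single genes with age in wild type. The homeostatic genes Cst3 and Mertk rose (0.23 each), 2 of 25, and Mertk also counts among phagocytosis genes. Apoe and the chemokine gene Ccl6 (−0.65) were the disease-associated genes that fell (2 higher and 5 lower adjusted over the list alone), Smpdl3a rose and Apoe fell among cholesterol efflux genes, and the stress gene Gadd45b (−2.43) fell among genes of the response to histone deacetylase inhibitors (3 adjusted over the list alone). Adjusted over the list alone, 4 interferon response genes were lower, 2 complement genes higher, 2 blood-brain barrier genes lower, 2 antigen presentation genes higher and 1 lower, and 1 NF-κB gene each way. Removal of WT_1m_Un M_1 left 20 genes and removal of WT_3m_TCF M_1 gave 227, without batch 1, 2, 3 or 5 it was 7, 69, 36 and 64, and the count stayed at 116 without both libraries of doubtful label, with 66 shared.

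Kbk microglia-like cells aged in part along the same genes. A total of 40 genes changed, 23 higher and 17 lower (877 at an unadjusted p under 0.05, 34 by DESeq2), and both groups shared 2 batches. Klk8 rose from 27.3 ± 7.05 to 114 ± 19.9 CPM (2.14, adjusted p = 7.60e-11), followed by Mlph (0.88), Lrrc3 (0.71), the transglutaminase gene Tgm2 (1.18), Srgn (1.12), Cd34 (1.09), the calcium channel gene Trpm2 (1.07), Cdh23 (0.86), Ebf3 (0.84), Padi2 (0.70) and Mctp1 (0.65). Lyz2 also rose (1.30, 130.4 ± 73.4 against 55.9 ± 10.3 CPM, adjusted p = 0.0220), with 272 CPM in the library labelled Kbk_3m_Un M_1, and without that library and its counterpart it did not pass (0.69). Pcp4 (−1.29), Rgs7bp (−0.96), Nab2 (−0.95), Cpq (−0.77), Fyn (−0.73), the activation marker Cd83 (−0.71), Rhoc (−0.69), Rcan1 (−0.69), the glycolytic enzyme gene Ldha (−0.36), Ssr2 (−0.31), Epb41l2 (−0.27) and Ybx1 (−0.25) fell, in 2 of 2 batches except Cpq (1 of 2). With different mice, Bmi1, Cdc42ep3, Ildr2, Klk8, Lrrc3 and Mlph rose in both genotypes (6 genes, 0.0999 by independence), and Epb41l2, Fyn, Lmnb1 and Pcp4 fell in both (4 genes, 0.112 by independence). Independence sets too low a baseline here as well, since the same fit served both comparisons. Of the genes called in wild type, 45 of 46 higher and 65 of 70 lower had the same sign in Kbk. Whether the age effect differs between genotypes was not tested.

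Within lists, the age comparison in Kbk changed Lyz2 among disease-associated genes (5 higher and 4 lower adjusted over the list alone), the integrin Itgb2 (0.37, along that direction in 1 of 2 shared batches) among phagocytosis genes (2 higher) and Ldha among glycolysis genes (2 lower). Cell cycle genes had 0 past the threshold and 11 lower adjusted over the list alone (adjusted p = 0.496 with an estimated correlation), and ribosomal protein genes 0 and 4 lower (adjusted p = 0.661 with an estimated correlation). Also over the list alone, 1 complement and 2 antigen presentation genes were higher, and 3 NF-κB, 2 immediate-early, 2 cholesterol efflux and 1 blood-brain barrier genes were lower. Without both libraries of doubtful label 17 genes remained, 14 of them shared with the 40. Without the library labelled Kbk_3m_Un M_1 alone the count was 15, and without WT_3m_TCF M_1 it was 76. Without batch 1, 2, 3, 5 or 7 it was 8, 16, 15, 16 and 11, and without batch 4 it was 83.

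**Figure D5:**
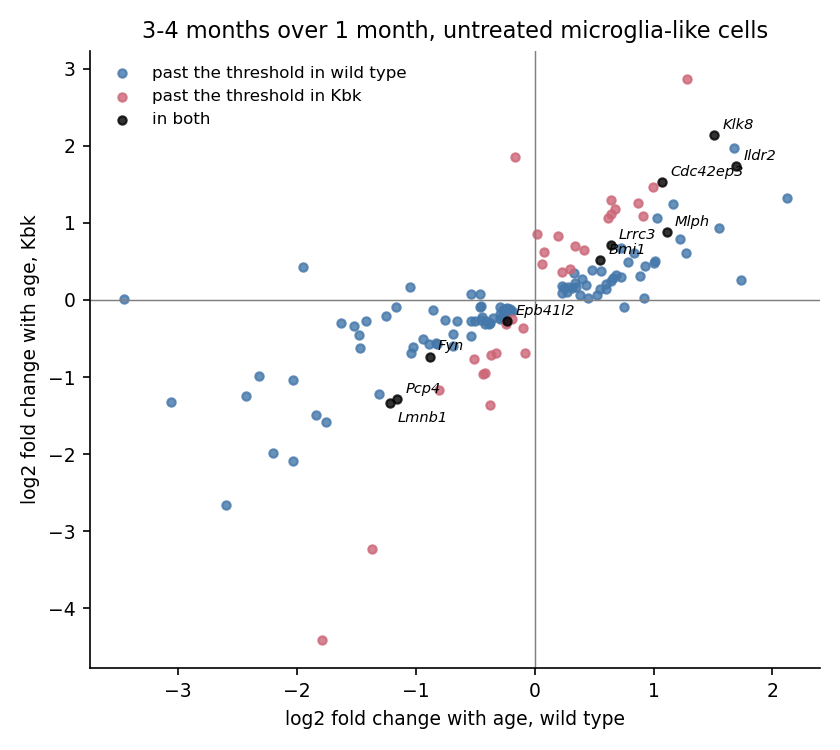
Change with age (3 to 4 months over 1 month, untreated) in microglia-like cells, log2 fold change in wild type (horizontal) against Kbk (vertical), 6 mice per group. Points are genes past the threshold in wild type (116), in Kbk (40) or in both, with Cxcl10 left out because it was detected in few mice.

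In vascular cells, single comparisons called more genes for age than for genotype or treatment. In endothelial-like cells 138 genes changed with age in wild-type mice (66 higher and 72 lower, 131 by DESeq2) and 77 in Kbk mice (42 and 35, 92 by DESeq2). The receptor gene Aplnr fell in both, from 28.7 to 3.94 CPM in wild type (−2.99, adjusted p = 1.03e-04) and by 2.98 on the log2 scale in Kbk (adjusted p = 0.00206), and the xanthine-oxidising enzyme gene Xdh rose in both (2.13, from 22.1 ± 9.50 to 117 ± 52.3 CPM, and 1.99). In wild type the largest other changes were Lypd1 (2.14), the heat shock gene Hspa1a (2.13), the matrix proteoglycan gene Bgn (−2.31) and Rbms3 (−2.10). In Kbk they were the interferon-induced gene Ifi27l2a (3.11, 93.8 against 7.58 CPM), H2-Q7 (2.74), the basement membrane gene Nid2 (−1.63) and Lcp1 (−1.63). Without both libraries of doubtful label the counts were 85 and 60.

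In mural-like cells the elastin gene Eln fell with age in both genotypes, among 39 genes changed in wild type (10 higher and 29 lower) and 35 in Kbk (8 and 27). Eln fell from 599.6 ± 198 to 163 ± 126 CPM in wild type (−2.20, adjusted p = 8.84e-05, 4 against 4 mice) and from 579 ± 170 to 159 ± 80.1 in Kbk (−1.81, adjusted p = 1.27e-04, 5 against 5 mice). Wild-type cells also lost Ecscr (−2.07) and the collagen gene Col3a1 (−2.01) and gained Ptgds (2.80), Ajap1 (2.26) and Slc16a12 (2.04), and Kbk cells lost Fmod (−2.25) and Nrep (−1.59) and gained the metabolic coactivator gene Ppargc1a (2.85), Cmbl (1.54) and Hlf (1.396). Without both libraries of doubtful label 21 and 20 genes changed.

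In single comparisons, genotype and treatment moved few genes in the vascular classes. Averaged over 5 settings, a measure chosen after the results were seen, genotype changed 36 genes in endothelial-like cells with all mice and 124 without both libraries of doubtful label, and 0 and 1 in mural-like cells. Between 3-month genotypes, mural-like cells of Kbk mice held more of the matrix gene Thbs1 (2.38, 162 ± 61.6 against 36.1 ± 22.95 CPM, adjusted p = 0.0172) and less of the prostaglandin synthase gene Ptgds (−2.93, 49.3 against 356 ± 389 CPM, adjusted p = 0.00782), 2 genes in all. In wild-type mural-like cells Ptgds was lower (−3.02, adjusted p = 0.00129) and Camk2g higher (0.73) with vorinostat than in the untreated mice, whose Ptgds varied as just given, and 1 gene passed without both libraries of doubtful label. The vorinostat effect against untreated mice differed between genotypes at 4 genes (Ptgds 3.72, Mndal 2.38, Casq2 2.23 and Thbs1 −3.60) and at 2 without both libraries, while DESeq2 called 17 others. In wild-type endothelial-like cells the matrix protein gene Sparc was higher with PEG than without treatment (0.72, 2462 ± 335 against 1554 ± 232 CPM, adjusted p = 0.00912). The interferon-induced gene Ifi203 was lower with vorinostat (−1.95, adjusted p = 0.0289), where 0 genes passed under the margin rule, the stricter cell filter, the ambient-scaled rule or without both libraries. In endothelial-like cells 2 genes differed between 1-month genotypes, among them Tmeff1 (0.75, adjusted p = 0.0484), and 0 passed without a batch term or under the same rules and filter. The remaining 10 of 15 comparisons in each of these classes gave 0 genes by edgeR, with 308 to 510 genes at an unadjusted p under 0.05 in endothelial-like cells (at most 1 by DESeq2) and 260 to 505 in mural-like cells (at most 8 by DESeq2).

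Choroid-plexus-like cells changed at single genes. With age in wild type 9 genes changed, including the lipid desaturase gene Scd1 (0.72), Rdh5 (0.57), Cox17 (0.37), Defb9 (−1.51), Npnt (−1.47) and Pld5 (−0.99). In Kbk 3 fell, Ndn (−1.49, adjusted p = 0.00247) and the muscle genes Tagln (−4.98) and Acta2 (−4.13), whose 1-month levels vary widely between mice. In wild type 6 genes were lower with HPBCD than with PEG, among them the glutamate transporter gene Slc1a2 (−3.15, 3.99 ± 1.86 against 24.4 ± 21.5 CPM, adjusted p = 0.0142, 3 against 5 mice), and under the hashtag rule scaled to ambient levels it did not fall (0.21). Vorinostat-treated Kbk mice differed from untreated wild-type mice at 6 genes, 5 higher and 1 lower, including Slc35f1 (1.51, adjusted p = 0.0472), and at 1 without both libraries of doubtful label. The other 7 of 11 comparisons gave 0 by edgeR (346 to 629 genes at an unadjusted p under 0.05, at most 1 by DESeq2).

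Tested as whole sets with a preset correlation, 96 of 390 pairs of list and comparison shifted in microglia-like cells, 71 of 390 in endothelial-like, 57 of 390 in mural-like and 59 of 286 in choroid-plexus-like cells. With an estimated correlation 0 of these shifted in any of the 4 classes.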

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

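Tests of exchanged labels, and the hashtag test beside it, were chosen after the result was seen, as were the 9 measures on which single mice were compared, and the other tests here were written before their outcome was known.

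Apoe, Lyz2 and other genes were lower in Kbk microglia-like cells at 1 month, and Apoe in WT_1m_Un M_1 stood apart at 3498 CPM against 922 to 1602 in the other mice of its group. For Apoe, RNA or cells of border macrophages is argued against. Their markers Pf4, Cbr2, F13a1, Ms4a7, Cd163 and Lyve1 made 6064 CPM in that class. In microglia-like cells these 6 summed to 2.32 CPM in Kbk and 2.84 in wild type. Fitted with sex and batch they rose by 0.177 CPM (SE 3.11), −0.00155 (SE 0.0272) times the fall Apoe would need. Mrc1, not among them, held 15.7 to 47.9 CPM in Kbk and 11.8 to 45.0 in wild type. A single wild-type mouse as the source of the fold changes is argued against as well, since the median log2 fold change of the 12 most-fallen named genes kept 0.901 of its size at worst (−1.003 against −1.11, without WT_1m_Un M_1), and the median of all 51 fallen genes, a check added later, kept 0.746 (−0.70 against −0.94). These genes were picked from the same mice by their falls, and fewer genes passed the threshold without WT_1m_Un M_1. Cells of other mice under one hashtag do not account for it either, since the ambient-scaled hashtag rule kept 0.8291 of the median fold change. What stays open is an effect of the genotype and, beyond Apoe, border macrophage RNA. RNA of monocytes, T and NK cells stays open too, untested as a source (summed markers 65.9 and 0.484 CPM in Kbk against 87.2 and 56.8 in wild type). The T and NK value in wild type rests on few mice, while leaving out any single wild-type mouse kept most of the median fall.

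Between the untreated 3-month genotypes 0 genes passed the threshold in microglia-like cells, with a pair of male libraries of batch 1 out of place. Exchanged labels of 2 mice of batch 1 is a candidate explanation: in endothelial-like cells the position of the library labelled Kbk_3m_Un M_1 minus that of the library labelled WT_3m_Un M_1 was −0.723, where the correct order would give a positive value, and 29 of the other 32 mice lay on their own side. As a test of the hypothesis alone, exchanging both labels gave 180 genes. The other 35 exchanges of a Kbk with a wild-type mouse of these groups gave at most 19. Leaving both out gave 84, against at most 18 for the other 35 pairs. The pair was picked for its levels of genotype genes, which raises both its counts by construction. Cells of other mice under one hashtag is argued against, since the difference in microglia-like cells kept 0.985 of its size under the ambient-scaled rule. What stays open is the age, since over 55 genes that change with age the library labelled WT_3m_Un M_1 stood at 0.430 between 1 month (0) and 3 to 4 months (1), under the 0.795 to 0.913 of the other 3 untreated 3-month mice of its batch, and an exchange between mice of one age does not explain that value.

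Microglia-like cells of WT_3m_TCF M_1 lay apart, 92.3% of them (347 of 376, 95% Wilson interval 89.1% to 94.6%) in cluster 13 against 2.17% to 5.25% in the other mice of its group. They held more Pik3ip1 (192 against 4.74 CPM in 7 mice of the batch), Gpr65, C5ar1 and the glucocorticoid-response genes Fkbp5 (316 against 62.0 CPM) and Klf9, and less Olfml3 (305 against 1596 CPM) and Npnt. A library-wide depth difference could contribute, since its median of 6827 UMIs per cell ranked 8 of 8 in its batch (others 7409 to 12522). Activation during cell isolation cannot be told apart: in endothelial-like cells 0 of 2 stress lists were the highest of the batch, but in microglia-like cells the immediate-early list was the highest (4.62 against at most 4.51 mean log2 CPM) and the heat shock list ranked 7 of 8 (5.722, others 5.72 to 6.71), so activation limited to microglia-like cells would have escaped the test as written. Other mice with vorinostat did not share the state, and no biological explanation was tested.

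Single mice also stood out from their group in other measures, where chance alone marks about 1 in 20 groups and 11 marks arose among 90 groups. Choroid-plexus-like cells made up 54.8% of Kbk_1m_Un F_3 (278 of 507 cells, 95% Wilson interval 50.5% to 59.1%, others 3.64% to 19.5%), a mouse whose median of 45383 UMIs per cell was far above the 9346 to 12068 of the others. Cell cycle genes averaged 3.82 log2 CPM in microglia-like cells of WT_3m_Un F_3 (others at most 2.37), 3.76 in Kbk_3m_HPBCD M_3 (1.98), 3.59 in WT_3m_PEG F_3 (1.92), 3.32 in WT_3m_HPBCD F_1 (1.71) and 2.91 in Kbk_3m_Un F_1 (2.10). WT_3m_Un F_3 also had 4.05% of its microglia-like cells (10 of 247, 95% Wilson interval 2.21% to 7.29%) in cluster 13, against 0.641% to 1.78% in the others. WT_3m_TCF F_2 gave 1343 filtered singlets against 528 to 781. The intervals cover counting error only.

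In mural-like cells the vorinostat effect against untreated mice differed between genotypes at 4 genes by an interaction test. Antibody tags that no mouse carries also gave counts, namely H-HTO-2 with 13742, 5012, 3047, 6326 and 1789 counts in batches 1, 2, 4, 6 and 7, beside 10972927 counts of the tags in use in batch 1, and M-HTO-5 with 33 in batch 8.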

How the results depend on the processing

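The lower level of Kmt2d kept its direction and passed under DESeq2 and without a batch term in all 4 classes (8 of 8 values). Tests of shares gave 0 calls in 6 of 6 alternatives, which says nothing about stability for the permutation tests, since no single one of them could pass, and the edgeR count model with batch gave 0 as well. Counts of changed genes in microglia-like cells stayed within 1.5 times the reported count in 271 of 375 recomputations and moved in 104, those of other classes in 60 of 114 and 54. Under RLE scaling, a minimum of 50 cells and without Kbk_1m_Un F_3 all 15 microglia counts stayed. Of 3839 recomputed values of 211 named genes, 2823 kept direction and call, 1010 kept direction but no longer passed, 5 passed anew and 1 changed direction. Across 25 settings the genes shared with the reported ones, always in the same direction, numbered 25 to 76 of 76 for the 1-month genotypes, 1 to 54 of 54 for vorinostat-treated Kbk against untreated wild-type mice, 5 to 116 of 116 for age in wild type and 6 to 40 of 40 for age in Kbk. Except where fewer mice or more genes were tested by construction, the cause was not tested. Which settings were chosen after seeing the data is stated above. The margin rule and the stricter cell filter were not run for mural-like and choroid-plexus-like cells, where the model could not be fitted.

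Without a filter on low counts, which roughly doubles the genes tested, microglia counts became 254 for the 1-month genotypes (76 reported) and 65 for the 3-month genotypes (0). Among Kbk mice they became 28 for vorinostat against untreated, 11 against HPBCD, 20 for HPBCD against PEG and 68 for PEG against untreated (each 0), and among wild-type mice 75 (0), 62 (1), 29 (6) and 29 (0) in the same order. Vorinostat-treated Kbk against untreated wild-type mice gave 212 (54), age 328 in wild type (116) and 191 in Kbk (40), and the interactions 34 against untreated and 35 against HPBCD (0 each).

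Without a batch term, microglia counts were 31 for the 1-month genotypes, 1 for vorinostat against untreated and 0 for HPBCD against PEG in wild type, 37 for age in wild type and 1491 for the genotype average (613). Choroid-plexus-like cells gave 0 for HPBCD against PEG (6), 0 for vorinostat-treated Kbk against wild type (6) and 2 for age in wild type (9). Endothelial-like cells gave 0 for the 1-month genotypes (2), 1 for the 3-month genotypes (0), 1 for vorinostat against HPBCD in wild type (0) and 146 for age in Kbk (77). Mural-like cells gave 1 for the 3-month genotypes (2), 1 for vorinostat against untreated in Kbk (0) and 9 in wild type (2), 1 for PEG against untreated in wild type (0) and 31 for the interaction against untreated mice (4). List shifts that turned around were ribosomal proteins for vorinostat against untreated in Kbk (adjusted p 0.00357 to 0.2135), interferon response (0.0131 to 0.698) and oxidative phosphorylation (0.0371 to 0.00301) for vorinostat against HPBCD in Kbk, and interferon response (0.00679 to 0.675), lysosome (0.00275 to 0.910) and cell cycle (8.89e-06 to 0.698) for PEG against untreated in wild type. So did mitochondrially encoded genes with age in wild type (3.60e-05 to 0.7499) and in Kbk (0.0280 to 0.783), and oxidative phosphorylation in the interaction against HPBCD (0.00944 to 0.119). Of 384 recomputed single list shifts, 120 stayed, 255 no longer passed and these 9 turned.

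DESeq2 called 2 microglia genes for the 3-month genotypes, 1 for vorinostat against HPBCD and 1 for HPBCD against PEG in Kbk, 1 for HPBCD against PEG in wild type and 1 for the interaction against HPBCD. In choroid-plexus-like cells it called 1 for vorinostat against HPBCD and 1 for HPBCD against PEG in Kbk, 1 for PEG against untreated in wild type, 26 for vorinostat-treated Kbk against wild type and 33 for age in wild type. In endothelial-like cells it called 1 for either genotype comparison, 1 for vorinostat against HPBCD, 1 for HPBCD against PEG and 2 for PEG against untreated in wild type. In mural-like cells it called 2 for the 1-month genotypes and, in wild type, 5 for vorinostat against untreated, 8 against HPBCD, 4 for HPBCD against PEG and 1 for PEG against untreated, with 17 and 2 for the interactions.

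The ambient-scaled hashtag rule gave 1 microglia gene for vorinostat and 1 for PEG against untreated in Kbk, 0 for vorinostat against HPBCD and 0 for HPBCD against PEG in wild type, 86 for vorinostat-treated Kbk against wild type and 66 for age in wild type. In choroid-plexus-like cells it gave 0, 0, 38 and 0 for HPBCD against PEG, vorinostat-treated Kbk against wild type, age in wild type and age in Kbk, with Slc1a2 at 0.21 instead of −3.15. Endothelial-like cells had 0 for the 1-month genotypes and 0 for vorinostat against untreated in wild type, and mural-like cells 10 for age in Kbk. The margin rule gave 0 for vorinostat against HPBCD, 0 for HPBCD against PEG and 185 for age in wild-type microglia-like cells, 21 for age in Kbk, and 0 for both endothelial comparisons just named. Its counts for untreated 3-month wild-type mice include cells of other mice given to WT_3m_Un M_2. The stricter cell filter gave 2 for the 3-month genotypes and 23 for age in Kbk in microglia-like cells, and 0, 0, 89 and 51 in endothelial-like cells for the 1-month genotypes, vorinostat against untreated in wild type, age in wild type and age in Kbk.

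Fitted on only the groups compared, microglia counts were 1 for the 3-month genotypes, 7 and 3 for vorinostat against untreated and HPBCD in Kbk, 3 for HPBCD against PEG and 12 for PEG against untreated in Kbk, 0 for vorinostat against HPBCD and 2 for PEG against untreated in wild type, 27 for age in wild type and 78 in Kbk. With the replicate number as a block they were 2 for the 3-month genotypes and 0 for HPBCD against PEG in wild type. After adjustment for batch but not sex, mice of the same number, always of the same sex, were more alike than mice of different numbers (mean r 0.151 against −0.0304), and 200 of 270 same-number pairs were over 0.1. Values were centred per group, which ties the second mean to the first. The numbers were not taken to pair the mice, since not every pair was over 0.1 (lowest −0.184) and 9 of 60 mice were on average most alike to mice of their own number. Without batches 2 and 3, and so with fewer mice, they were 25 for the 1-month genotypes, 0 for vorinostat against HPBCD and 0 for HPBCD against PEG in wild type, 1 for vorinostat-treated Kbk against wild type, 26 and 7 for age in wild type and Kbk, and 349 for the genotype average.

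With single mice, the doubted pair or each batch left out, microglia counts ranged from 36 (batch 2) to 144 (WT_3m_TCF M_1) for the 1-month genotypes and from 0 to 84 (both libraries of doubtful label) for the 3-month genotypes. They ranged from 0 to 1 for vorinostat against untreated in Kbk and from 0 to 3 in wild type, from 0 to 1 for vorinostat against HPBCD and from 0 (batch 8) to 8 for HPBCD against PEG in wild type, and from 0 to 2 for the interaction against untreated mice. For vorinostat-treated Kbk against wild type the range was 13 (batch 2) to 151 (WT_3m_TCF M_1), for age in wild type 7 (batch 1) to 227 (WT_3m_TCF M_1) and for age in Kbk 8 (batch 1) to 83 (batch 4). Without the doubted pair, choroid-plexus-like counts were 1 for vorinostat-treated Kbk against wild type, 4 for age in wild type and 1 in Kbk. Endothelial-like counts were 1 for the 3-month genotypes, 0 for vorinostat against untreated and 85 for age in wild type. Mural-like counts were 1 for vorinostat and 1 for PEG against untreated in wild type, 3 for vorinostat-treated Kbk against wild type, 21 and 20 for age in wild type and Kbk, and 2 for the interaction. The correlation that asks for a reversal of the genotype difference was 0.0846 without the pair and −0.286 with all 6 shared mice on both sides, which builds a negative value in, against 0.128 reported. Shifts of lists with an estimated correlation or by fry numbered 0 each, against 96.

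Depth limits what could be seen. Microglia-like cells of 49 to 521 per mouse let the simulated test recover 49.3% of genes changed 1.5-fold at 1 month, and endothelial-like cells 32.8%.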

Other observations

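The average over settings, its tests and the reversal without the doubted libraries were chosen after the results were seen, while the test of genes near Kmt2d was written before its outcome was known. Averaged over the 5 settings of age and treatment, more homeostatic genes rose than fell in Kbk microglia-like cells, and more disease-associated genes fell than rose, with no set test run on the average. Of 25 homeostatic genes 10 rose and 0 fell (Mertk, Cst3, Fcrls, Tgfbr1, Sall1 and Mef2c among them), or 13 rose and 1 fell adjusted over the list alone. Of 23 disease-associated genes 8 fell (Lyz2, Apoe, Axl, Itgax, Cst7, Cd68, Ctsl and Fth1) and Ccl6 and Timp2 rose, or 4 rose and 9 fell adjusted over the list alone. The NF-κB genes Il1b, Tlr2, Ccrl2, Ccl2 and Nfkbia fell, 5 of 17, as did the interferon response genes Bst2, Ifit1 and Ifit3 (3, or 7 adjusted over the list alone), while the TGF-β pathway genes Tgfbr1, Tgfbr2 and Itgav rose. Among genes of isolation stress, the immediate-early genes Zfp36, Junb and Dusp1 fell (3 of 17, or 5 adjusted over the list alone), as did the heat shock genes Hspe1 and Hsp90ab1 (2 of 13, or 4), and a difference in isolation was not tested as a source. Phagocytosis genes went both ways (5 rose and 6 fell).

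A total of 613 genes changed in this average, 287 higher and 326 lower in Kbk (1855 at an unadjusted p under 0.05). Mrc2 fell from 22.4 to 4.55 CPM (−2.11, adjusted p = 2.11e-13), Lyz2 from 259.8 ± 69.0 to 77.9 ± 42.8 (−1.71) and Apoe from 972 to 592 (−0.81), beside Mrc1 (−1.53, 10.2 ± 12.4 against 21.9 ± 25.8 CPM, lower in 4 of 5 settings), Ifi30 (−1.12), Lsp1 (−1.03), Emp3 (−0.93), Igfbp4 (−0.93) and Cd52 (−0.86). Col6a3 rose from 8.79 ± 5.45 to 26.8 ± 9.31 CPM (1.60), and Hlf (1.06), Actn1 (1.02), Pcp4 (0.95), Tmem44 (0.94), Khdrbs3 (0.75), Csmd3 (0.67) and Cmas (0.66) rose with it. Ccl5 (−3.79) was called here but not under the ambient-scaled hashtag rule (adjusted p = 0.0694). Without both libraries of doubtful label 827 genes changed, 602 of them shared, and endothelial-like cells went from 36 to 124 genes, choroid-plexus-like cells from 6 to 21 and mural-like cells from 0 to 1 (391 at an unadjusted p under 0.05 with all mice, 0 by DESeq2).

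The 75 genes of the 1-month genotype comparison other than Kmt2d kept their direction at 3 to 4 months in 70 cases without treatment, 74 with PEG, 73 with HPBCD and 70 with vorinostat, where simulated data without a shared effect reached 48, 54, 55 and 59 at most. Exact permutation of the mice gave p = 0.0195 without treatment and 0.00216 in the other 3 settings, the smallest that 6 against 6 mice allow (adjusted p = 0.0195 and 0.00289). Values were adjusted for batch but mice permuted across batches. Genotypes share no batch with vorinostat and only some otherwise, so batch and genotype are confounded in full or in part. Leaving out both libraries of doubtful label moved the first count to 72, with 24 of the genes then past the threshold.

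Genes next to Kmt2d carried along with the mutant allele could mimic an effect of the mutation, and an excess of changed genes around Kmt2d was not seen. Among the 162 tested genes nearest to Kmt2d, 5 changed in the average (3.09%: Tspo, Parvb, Gpd1, Espl1 and Gpr84, all lower in Kbk), against 598 of 10177 others (5.88%), a ratio of shares of 0.525. The odds ratio was 0.510 (95% interval 0.163 to 1.22, Fisher's exact p = 0.173), and on chromosome 15 as a whole 19 of 398 changed (odds ratio 0.803, p = 0.444). Positions were matched for 97.6% of the 10594 genes. The test compares shares only, so it cannot exclude that a few carried genes matter.

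Whether vorinostat moves Kbk microglia-like cells back toward wild type was asked across genes, which are not independent replicates. Untreated Kbk mice enter both sides, so they were divided between the genotype difference and the treatment difference, which gave r = 0.128 (0.0761 to 0.177 over the divisions), against 0.0406 in simulated data without an effect. A reversal would give a negative r. With all 6 untreated Kbk mice on both sides r was −0.286, against −0.471 simulated, and the covariance exceeded the simulated one by 0.00966, or by 0.00895 with divided mice. Without both libraries of doubtful label the values were 0.0846 (0.0184 to 0.155, simulated 0.0401) divided and −0.352 (simulated −0.497) undivided, with a covariance difference of 0.00650 and 0.00769. No movement back was seen in these values.

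Each count of changed genes was set beside 30 splits of the same mice, the real one included. In microglia-like cells the real split alone reached its count for the genotype difference at 1 month (1 split as large, 76 genes against at most 28 in the others). So it did for vorinostat-treated Kbk against untreated wild-type mice (1, 54 against 4), for age in wild type (1, 116 against 39) and in Kbk (1, 40 against 7) and for the genotype average (1, 613 against 73). The same was seen for age in endothelial-like cells (1 split each, 138 against 19 in wild type and 77 against 3 in Kbk) and for age in mural-like cells (1 each, 39 against 13 and 35 against 7). A share of 1 of 30 is the smallest that 30 splits allow, and it was not adjusted over the results tested. Labels were also shuffled across batches, so these splits alone do not exclude chance. By a small margin the real split alone also reached its count for HPBCD against PEG in wild-type microglia-like cells (1 split, 6 genes against 4) and for the 3-month genotypes in mural-like cells (1, 2 against 1). Of those 6 genes, Cxcl9 and Cxcl10 rest on WT_3m_PEG M_2, and 0 genes passed without a batch term, under the margin rule, under the ambient-scaled rule or without batch 8. Chance cannot be excluded for vorinostat against HPBCD in wild-type microglia-like cells (8 splits, 1 gene against 4). Where the real count was 0 in microglia-like cells all 30 splits were as large, and the highest others were 5 for the 3-month genotypes, 0, 1, 2 and 0 for the treatments in Kbk (vorinostat against untreated, against HPBCD, HPBCD against PEG, PEG against untreated), 4 for PEG against untreated in wild type, and 2 and 1 for the interactions. For vorinostat against untreated wild-type mice 1 split called 70 genes in microglia-like cells and another 117 in endothelial-like cells (5 splits as large as the real 1), which points to a structure of these mice that was not identified.

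Nor can chance be excluded for the choroid-plexus-like counts (6, 3, 2 and 2 splits for HPBCD against PEG, vorinostat-treated Kbk against wild type, age in wild type and age in Kbk, with 6, 6, 9 and 3 genes against at most 28, 21, 29 and 3), for endothelial-like cells of the 1-month genotypes (2 splits, 2 genes against 2) and of PEG against untreated wild-type mice (2 splits, 1 against 1), or for mural-like cells of vorinostat against untreated wild-type mice (7 splits, 2 against 10) and of the interaction (6 splits, 4 against 7). Shifts of whole lists with the preset correlation were as frequent in other splits, with 96 against at most 103 in microglia-like cells (3 splits as large), 59 against 83 in choroid-plexus-like cells (20), 71 against 84 in endothelial-like cells (5) and 57 against 93 in mural-like cells (22).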
